A study of Mus musculus with 18 samples.

How the data were processed

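Messenger RNA of 18 mouse tissue libraries was sequenced as paired reads: 3 T2 primary tumors, 3 lung metastases, 4 normal mammary glands and 8 normal lungs. Libraries were assigned to groups from their titles. The deposited table held 26 columns, of which 18 matched these libraries by name, and 8 columns of other samples were not used. The submitters' processing notes name STAR, SAMtools and the genome build GRCm38, with no versions. The program that estimated the counts is not given in the sources used here. The scaling between libraries and the filter on genes are not described either, although abbreviations in the name of the table may stand for a quantile scaling and a percentage filter. The values the authors deposited are log2 of an estimated fragment count per gene times a factor for each library, as seen from the values themselves. No pseudocount was added, and a gene with a count of 0 is blank.

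Low values were mostly whole multiples of a step that differed between libraries, from 0.679 to 1.04, and the step was taken as the value of 1 fragment. On that basis the libraries held an estimated 61672538 to 86672380 fragments. Mammary glands had 73068367 to 81168200 and lungs 61672538 to 84850726. These depths are estimates from the normalized values, and intervals for counting error were not computed. Of 21735 rows, 1 had no gene name and held 0.0526% to 2.39% of the linear total of a library, and it was left out. After removal of 13 repeated symbols, 21721 genes remained. From 296 to 1227 genes were blank in a library. The table listed no gene with fewer than 11 values in the 18 columns used, so a gene detected in few libraries was not tested. No 2 libraries held identical values. Pearson correlations across 14286 genes, which are not independent replicates, were 0.990 to 0.993 between primary tumors, 0.976 to 0.988 between metastases, 0.842 to 0.992 between glands and 0.915 to 0.994 between lungs.

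Comparisons, gene lists, tests and most alternatives were chosen before the data were examined. Genes were tested with limma 3.58.1 (empirical Bayes with a trend on the mean, two-sided) in R 4.3.3 on the deposited log2 values, with blanks as missing and at least 2 values required in each group. Benjamini-Hochberg adjustment was applied over all genes tested, with a threshold of 0.05. The first 4 comparisons used only the 2 groups compared. The difference between the tumor-against-host contrasts at the 2 sites was fitted on all 18 libraries. A gene was called higher or lower in metastasis than in both primary tumor and lung by the larger p of those contrasts in that fit, where both had the same sign. The 30 gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with a correlation estimated per list and with the rotation test fry from limma with statmod 1.5.0. Camera compares a list with all other genes, while fry tests whether the genes of a list move on balance in a direction. Both used only genes with a value in every library of the fit. Counts and medians of a list used all its genes tested with limma, so a camera or fry result may rest on fewer genes than the count beside it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

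Genes named in the text follow a rule. They are Trp53 and, in each of the first 3 comparisons, the 8 genes with the largest fold in each direction among genes past the threshold whose groups do not overlap. Names of predicted or unnamed genes and genes of a list were left out of that ranking. For each list and comparison they include up to 2 members with the largest fold in each direction among those past the threshold, or the 2 with the smallest p where none passed. For the last pair of tests the 5 largest in each direction were taken. The text names part of the genes the rule gives. Levels of such a gene in a group may be given outside the comparison that named it. Axin2 and Stat3 as single genes in the metastasis comparison fall outside the rule. Gene positions are those of the GENCODE annotation of GRCm38, in which all 336 genes that the rule gives were found by symbol.

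The share of lung RNA in a metastasis was estimated on the linear scale from 24 alveolar and airway genes at least 8 times higher in lung than in primary tumor, as the median over genes of the metastasis excess over primary tumor divided by the lung excess. It is approximate on normalized values. The tests were tested on simulated data. Each gene had its mean over all libraries and an SD pooled over all groups, and 67, 67 and 66 genes were changed by 1, 2 and 4. Spreads differed between the real groups, and far more genes were called there. The shares recovered are therefore not the power of the real comparisons. For metastasis against primary tumor, 22.4%, 55.2% and 81.8% of genes changed by 1, 2 and 4 on the log2 scale were recovered, with 4 unchanged genes called of 20701 (3.64% of the genes called). The corresponding shares were 40.3%, 52.2% and 74.2% for primary tumor against mammary gland and 49.3%, 70.1% and 87.9% for metastasis against lung. Unchanged genes made up 6.12% of the genes called for metastasis against lung and 6.61% for the difference between the tumor-against-host contrasts at the 2 sites. A shift of the proliferation list by 1 was recovered in all 5 comparisons with either correlation, and with the preset correlation no other list was called. Noise was drawn independently for each gene. The list simulation therefore cannot show how either correlation performs where genes of a list vary together, as in real tissue.

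Alternatives were another scaling (a common median per library, or a further quantile normalization), 16 added on the linear scale, a filter on low values, limma without the trend or with library weights, a minimum fold, all groups in one fit, the tumor number as a block, subsets of glands and lungs by run or strain, primary tumors mixed with lung, and each library left out in turn. Fits without lungs 7 and 8 or glands 3 and 4, or with their shared number endings as a block, were added after seeing the data.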

Results

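RNA was sequenced from tissue pieces of a transplanted mouse breast tumor at 2 sites and of normal mammary gland and lung. Host tissue here means normal tissue of the same organ, and the labels do not say that it came from tumor-bearing mice. The tumor is T2, a basal-like, p53-null line of mammary tumors kept by transplantation into mice of the same strain and used as a model of triple-negative breast cancer. The table held 3 primary tumors, 3 spontaneous lung metastases, 4 normal mammary glands and 8 normal lungs. The tumor libraries of both sites carry the numbers 3817, 3819 and 3820 in their labels, so same-numbered libraries may come from the same animal. Lungs 1 to 3 came from BALB/c mice and lungs 4 to 6 from FVB mice, while the labels give no strain for lungs 7 and 8 or for the glands. Glands 3 and 4 carry numbers in their labels with the same ending as those of lungs 7 and 8, so these may come from the same 2 animals. Values were log2 levels of 21721 genes. The low values of each library gave an estimated depth of 61672538 to 86672380 fragments per library, with 76947221 to 79547256 in the primary tumors and 69310848 to 86672380 in the metastases. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries. The study asks how Wnt and STAT3 pathway genes and the immune cells around the tumor differ between primary tumor and metastasis.

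Trp53, the gene deleted in this tumor line, lies on chromosome 11 from 69580359 to 69591873 in GRCm38. Its log2 level was 12.83 ± 0.11 (SD, n = 3) in primary tumors and 12.68 ± 0.16 (SD, n = 3) in metastases. It was 11.92 ± 0.50 (SD, n = 4) in mammary glands and 11.57 ± 0.20 (SD, n = 8) in lungs. The 6 tumor libraries were higher than the 12 normal libraries by 1.07 on the log2 scale, with p = 5.387e-05 in a two-sided exact permutation test, the smallest p that the 18564 permutations allow. The test treats every library as independent, although some may share an animal. A level per gene also counts fragments from parts of the gene outside a deletion, so it does not check the deletion.

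Metastases were compared with primary tumors first. Genes induced by interferon and genes of antigen presentation were higher in the metastases. All 26 genes of the interferon response list rose, with a median log2 fold of 3.43, and the mean level of the list was 8.54 ± 0.23 in primary tumors and 12.27 ± 0.81 in metastases (SD, n = 3 each). All 15 genes of MHC class I presentation rose (median 3.35), as did all 10 genes of MHC class II presentation (median 4.32). In camera the 3 lists had adjusted p = 3.28e-11, 6.25e-11 and 3.93e-08, and adjusted p = 0.384 with an estimated correlation for each. Cxcl9, a chemokine that attracts T cells, lies on chromosome 5 from 92321347 to 92328079 and rose from 7.89 ± 0.51 to 14.16 ± 0.73 (SD), a log2 fold of 6.27 ± 0.38 (SE; limma adjusted p = 5.48e-05). Nlrc5 and Ciita, the transactivators of MHC class I and class II genes, rose by 4.47 ± 0.21 and 5.01 ± 0.26 (SE; limma adjusted p = 3.15e-05 and 3.555e-05). The immunoproteasome gene Psmb9 rose by 4.33 ± 0.20 and the class II gene H2-Eb1 by 4.70 ± 0.20.

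Transcripts of immune cells rose as well. All 16 genes of the NK and cytotoxic list were higher in metastases (median log2 fold 4.42), and Prf1, which encodes perforin, rose by 5.83 ± 0.31 (SE; limma adjusted p = 3.56e-05). Of 23 T cell genes, 18 rose and 2 fell (median 3.44). Cd8a rose by 5.18 ± 0.42 (SE), while Tcf7 and Lat fell by 0.92 and 0.89. Of 16 B cell and plasma cell genes, 14 rose and 1 fell (median 4.10, or 2.49 against primary tumors mixed with 2.03% lung), with Jchain, the joining chain of secreted IgA and IgM, higher by 8.25 ± 1.17 (SE). The checkpoint list had 16 of 17 genes higher (median 2.19), among them Pdcd1, which encodes PD-1, by 6.27 ± 0.52 (SE; limma adjusted p = 0.000138). Camera gave adjusted p = 6.46e-07 for NK and cytotoxic genes, 7.42e-06 for T cells, 7.05e-05 for B and plasma cells and 5.88e-07 for checkpoints, and adjusted p = 0.384 with an estimated correlation for each of the 4. From alveolar and airway genes, the share of lung RNA in metastases 3817, 3819 and 3820 was estimated at 1.15%, 2.03% and 6.10%, and from endothelial and stromal genes at -0.06%, 0.49% and 1.33%.

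Among myeloid cells, 15 macrophage genes rose and 3 fell of 22 (median 1.48; camera adjusted p = 0.000613, and adjusted p = 0.477 with an estimated correlation). Aif1 and Gpnmb rose by 2.05 ± 0.17 and 2.17 ± 0.29 (SE), while Folr2, a marker of tissue-resident macrophages, fell by 2.69. Of 17 neutrophil genes 9 rose and none fell (median 1.45). Ltf, which is also a member of the luminal and secretory list, was higher by 6.45 ± 0.62, and Mmp8 by 4.98 ± 0.73 (SE). The neutrophil median was 0.97 (9 higher and 1 lower of 19) against primary tumors mixed with 2.03% lung. Of 13 dendritic cell genes 8 rose and 1 fell (median 2.17), with Clec9a, a marker of cross-presenting dendritic cells, higher by 4.20 ± 0.33 (SE). Neutrophil and dendritic cell genes had camera adjusted p = 0.0063 and 0.00297, and adjusted p = 0.384 with an estimated correlation for both. Of 10 alveolar macrophage genes 7 rose and 1 fell (median 1.77; camera adjusted p = 0.0371, and adjusted p = 0.384 with an estimated correlation). Against primary tumors mixed with 2.03% lung, 5 of 12 genes of this list were higher and 4 lower, and the median turned to -0.95. The chemokine list, with 11 of 30 genes higher and 3 lower, did not pass (camera adjusted p = 0.181), except without primary tumor 3820 (camera adjusted p = 0.0123) or with common medians (0.0116).

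**Figure D1:**
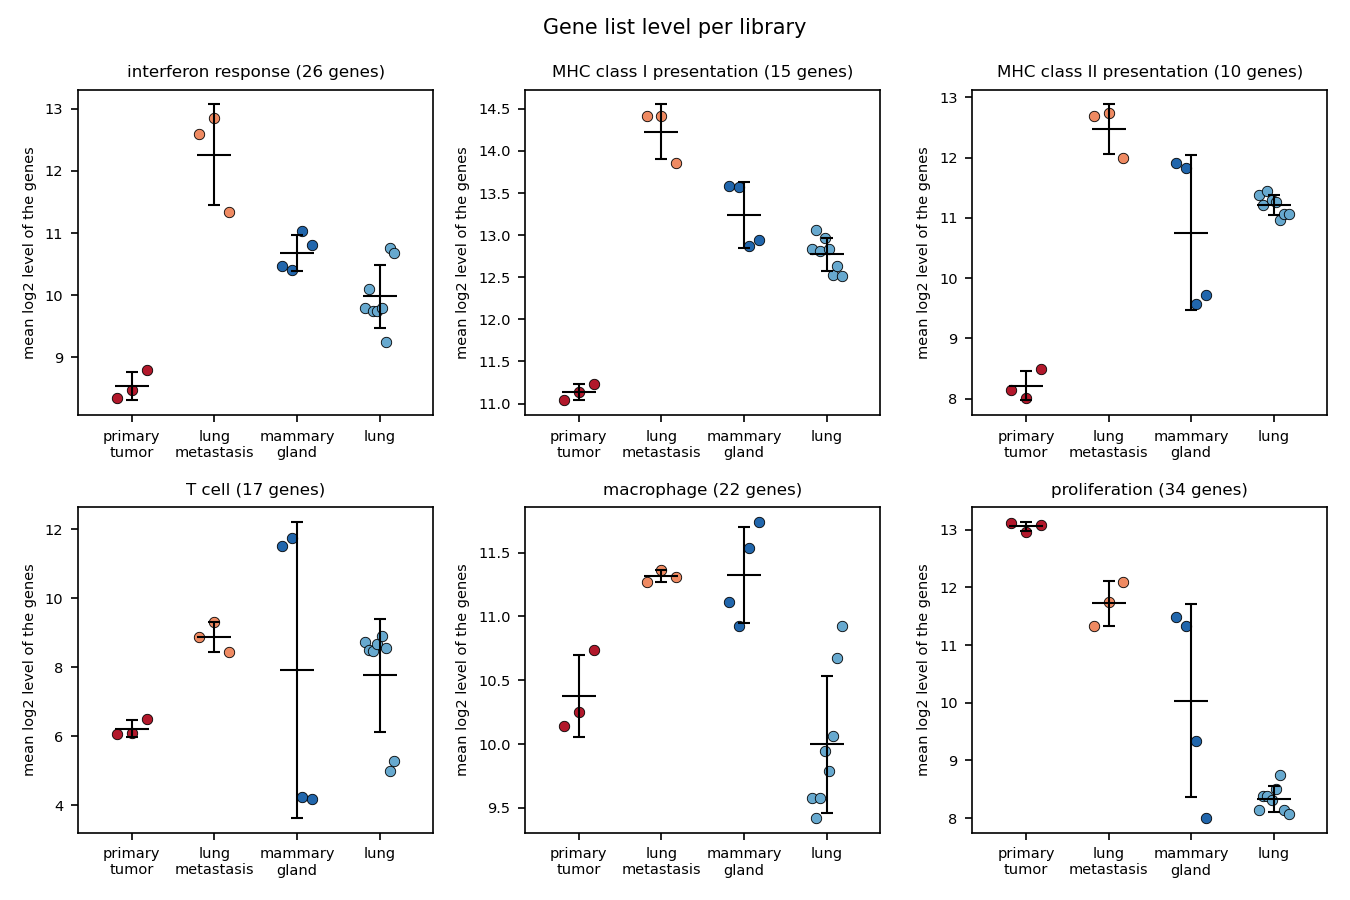
Each panel plots, for 1 gene list, the mean log2 level of its genes (y axis, those with a value in every library) in each library (points) of the 4 groups (x axis), with the group mean and SD as a horizontal line and bars. Primary tumors lie between 8.35 and 8.80 for interferon response and metastases between 11.34 and 12.86, and mammary glands 3 and 4 (4.24 and 4.17) and lungs 7 and 8 (4.99 and 5.27) lie below the other libraries of their group for T cell genes.

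Genes of cell division were lower in the metastases. All 34 genes of the proliferation list fell, with a median log2 fold of -1.40, and the mean level of the list was 13.05 ± 0.08 in primary tumors and 11.72 ± 0.39 in metastases (SD, n = 3 each). The list had camera adjusted p = 6.78e-16, and adjusted p = 0.384 with an estimated correlation. The mitotic kinesin Kif11 fell by 1.82 ± 0.23 (SE; limma adjusted p = 0.000693) and the spindle checkpoint kinase Bub1 by 1.71 ± 0.19 (SE; limma adjusted p = 0.000408). In metastases the list still lay above normal lung, at 8.34 ± 0.22 (SD, n = 8).

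Wnt target genes and Wnt ligand and receptor genes were lower in metastases on balance. Of 21 Wnt target genes 8 fell and 2 rose (median -0.24; camera adjusted p = 0.0135, and adjusted p = 0.384 with an estimated correlation). Tnfrsf19 fell by 1.96 ± 0.15 and the secreted Wnt inhibitor Wif1 by 1.97 ± 0.21 (SE; limma adjusted p = 0.000106 and 0.00036). Ccnd1 and Cd44 rose by 0.70 ± 0.15 and 0.58 ± 0.06 (SE), although Ccnd1 did not pass with common medians (limma adjusted p = 0.0877). Notum, which inactivates Wnt proteins, was 12.45 ± 0.11 in primary tumors and 10.70 ± 0.25 in metastases (SD). Axin2, singled out after its values were seen because it is a widely used Wnt readout, was 12.46 ± 0.15 and 12.25 ± 0.07 (SD), a log2 fold of -0.21 with limma adjusted p = 0.0877. Of 37 Wnt ligand and receptor genes 16 fell and 8 rose (median -0.37; camera adjusted p = 0.02, and adjusted p = 0.409 with an estimated correlation). Rspo4 fell by 4.58 and Wnt6 fell by 2.08. Wnt1 itself was at 12.32 ± 0.15 in primary tumors and 12.35 ± 0.16 in metastases (SD). Of 16 Wnt inhibitor genes 5 rose and 7 fell, and the list did not pass (camera adjusted p = 0.28).

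**Figure D2:**
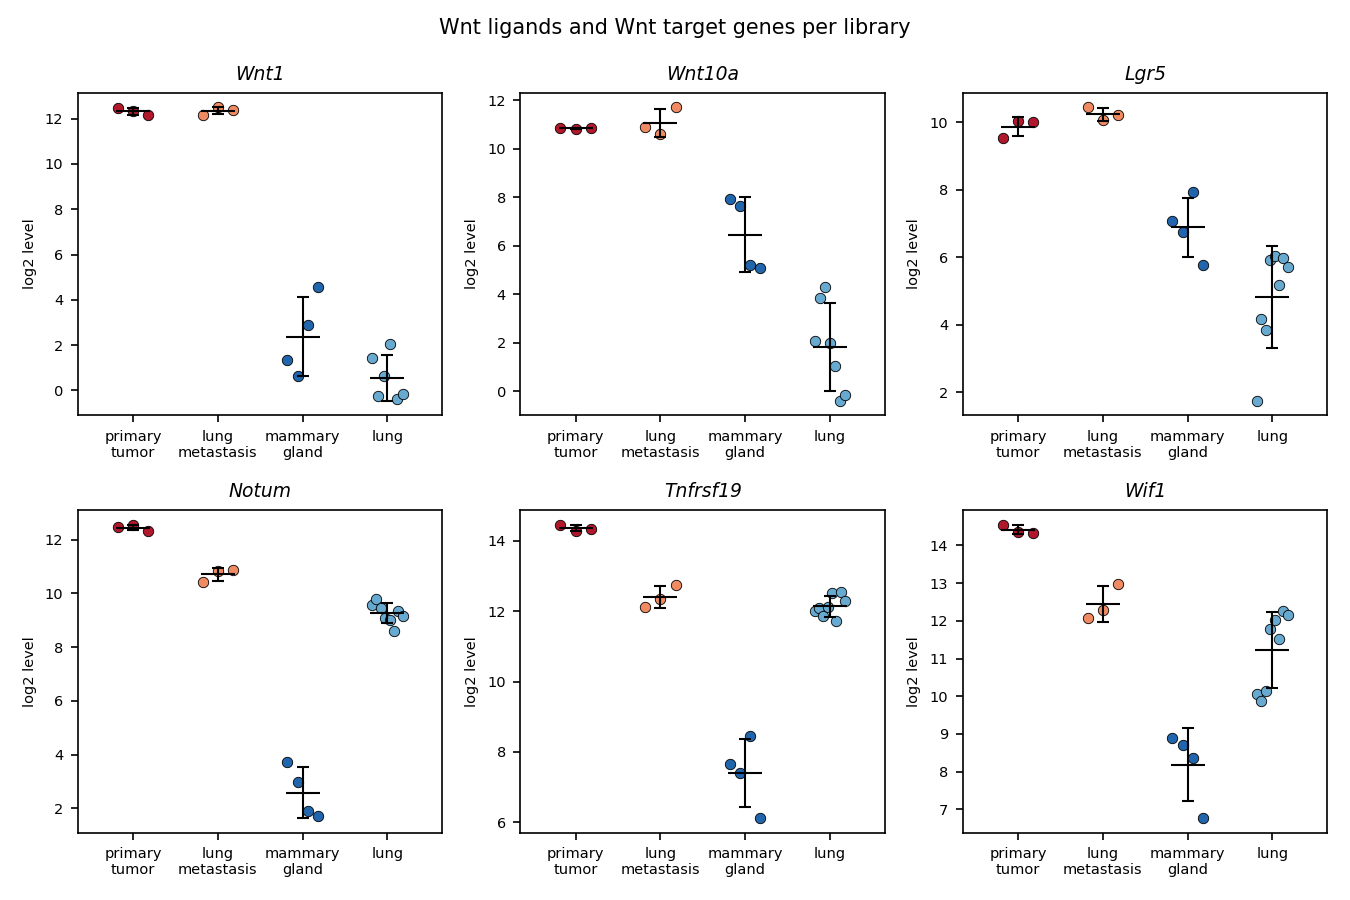
Log2 level (y axis) of 2 Wnt ligands and 4 Wnt target genes in each library (points) of the 4 groups (x axis), with the group mean and SD. Wnt1 lies between 12.17 and 12.50 in the 6 tumor libraries and at or below 4.57 in every normal library with a value, while Notum, Tnfrsf19 and Wif1 are lower in the 3 metastases than in the 3 primary tumors.

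Genes around IL6 and STAT3 moved upward in metastases. Of 31 genes of this list 14 rose and none fell (median 0.51; camera adjusted p = 0.00556, and adjusted p = 0.553 with an estimated correlation). The mean level of the list in metastases, 11.54 ± 0.04 (SD, n = 3), lay within the range of the lungs (11.22 to 11.65). Against lung without lungs 7 and 8, 15 genes of the list were higher and 13 lower of 32 (camera adjusted p = 0.769). Lcn2, which encodes lipocalin 2, was 12.83 ± 0.10 in primary tumors and 15.23 ± 0.32 in metastases (SD), a log2 fold of 2.40 ± 0.15 (SE; limma adjusted p = 6.34e-05). The receptor gene Tnfrsf1b rose by 2.44 ± 0.21 (SE). Stat3, singled out after its values were seen, was 14.07 ± 0.10 and 14.63 ± 0.03 (SD), with limma adjusted p = 0.000666.

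Stromal and epithelial genes also differed between the sites. Of 25 adipocyte genes 14 fell and 3 rose (median -0.98; camera adjusted p = 0.0063, and adjusted p = 0.502 with an estimated correlation), and Cfd fell by 8.56 ± 1.18 (SE). Of 24 fibroblast and matrix genes 8 fell and 3 rose (median -0.37; camera adjusted p = 0.0371, and adjusted p = 0.698 with an estimated correlation). Lum and Dcn, which encode matrix proteoglycans, fell by 3.69 and fell by 2.13, and Postn rose by 1.53 ± 0.29 (SE). Of 23 EMT genes 11 rose and 1 fell (median 0.45; camera adjusted p = 0.0416, and adjusted p = 0.663 with an estimated correlation). Cldn1, which encodes a tight junction protein of epithelia, rose by 2.90 ± 0.28 (SE), and the transcription factor gene Twist2 fell by 2.36. The EMT list pools junction genes of epithelia with mesenchymal regulators, so its balance does not tell more EMT from less. Alveolar and airway genes had 16 of 19 members higher and 3 lower (median 3.48; camera adjusted p = 0.000495, and adjusted p = 0.384 with an estimated correlation). Against primary tumors mixed with 2.03% lung on the linear scale, 5 of 26 genes of this list were higher and 6 lower (median 0.06), which is near 0 by construction, since the share was estimated from 24 genes of the list. Of 20 immediate early and handling stress genes 7 fell and 3 rose (median -0.35; camera adjusted p = 0.0371, and adjusted p = 0.687 with an estimated correlation). Hspa1a, a heat shock gene, fell by 2.96. The lists of hypoxia and glycolysis (4 of 22 higher), p53 targets (8 higher and 2 lower of 20), basal mammary epithelium (11 and 4 of 22), luminal and secretory mammary epithelium (9 and 4 of 24), lung endothelium and stroma (7 and 2 of 22), skeletal muscle (10 and 1 of 19), heart muscle (3 and 1 of 8) and blood (0 of 9) did not pass camera, with adjusted p from 0.0574 to 0.954. Skeletal muscle passed without primary tumor 3817 (camera adjusted p = 0.0379) and with common medians (0.0097), blood without primary tumor 3817 (0.0255) and lung endothelium without metastasis 3817 (0.0289). Against the same mixture with 2.03% lung, a share from alveolar and airway genes, lung endothelium and stroma had 2 higher and 16 lower of 25 genes. Skeletal muscle then had 5 higher and 8 lower of 19, heart muscle 1 and 7 of 10 and blood 0 and 6 of 9. The other lists that did not pass kept more genes higher than lower. Adjusted over the list alone, 22 of the 30 lists had the same counts as over all genes tested, and the largest change was in hypoxia and glycolysis, from 4 genes to 0.

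Outside the lists, the genes with the largest increases included Pigr, Igha and Ighg2b. Pigr, the receptor that carries IgA across epithelia, was at 10.10 ± 1.02 (SD, n = 3) in metastases. In the primary tumors it was at -0.40 and -0.41 in 2 libraries, about 1 fragment each, and blank in the remaining library. Igha was higher by 10.37 ± 1.49 and Ighg2b by 8.44 ± 0.87 (SE), both from gene families whose members share fragments, so single values are uncertain. The largest decreases included Pcsk2 (-5.81 ± 0.58), Cyp2e1 (-5.60 ± 0.44), Crabp1 (-5.39 ± 0.55), Lrrc15 (-5.35 ± 0.39) and the homeobox genes Hoxa9 (-5.18 ± 0.44) and Hoxc8 (-4.95 ± 0.51), each with its SE and limma adjusted p between 8.38e-05 and 0.000524. Lrrc15, a marker of activated fibroblasts, was 9.56 ± 0.33 in primary tumors, 4.21 ± 0.78 in metastases, 9.36 ± 1.58 in mammary glands and 3.97 ± 0.73 in lungs (SD). Hoxa9 was 6.31 ± 0.23 in primary tumors, 1.13 ± 0.78 in metastases and 9.41 ± 0.72 in glands (SD), and 5 of 8 lungs had a value.

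In total 5866 genes were higher and 3969 lower of 20701 tested (limma, Benjamini-Hochberg 0.05), of which 3223 and 945 changed at least 2-fold. All primary tumors were sequenced in one run and all metastases in another, so run and site cannot be told apart. With all 4 groups sharing one spread 4128 genes passed, and Kif11, Bub1, Cd8a and Prf1 did not (limma adjusted p = 0.103, 0.0885, 0.132 and 0.102). Setting every library to a common median moved the median fold of all genes by -0.33 and turned the counts to 3766 higher and 7686 lower, and a quantile normalization moved it by -0.13 and gave 4838 and 5077. Common medians ended the calls of Wnt ligands and receptors (camera adjusted p = 0.105), adipocyte (0.0563), EMT (0.082), fibroblast and matrix (0.115) and immediate early genes (0.0849). Of these, EMT was also lost without primary tumor 3817 (0.0848), metastasis 3819 (0.0504) or metastasis 3820 (0.0701). Fibroblast and matrix was lost without primary tumor 3820 (0.229), metastasis 3817 (0.0528) or metastasis 3820 (0.0557), and immediate early without primary tumor 3820 (0.105) or metastasis 3820 (0.116), in camera.

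**Figure D3:**
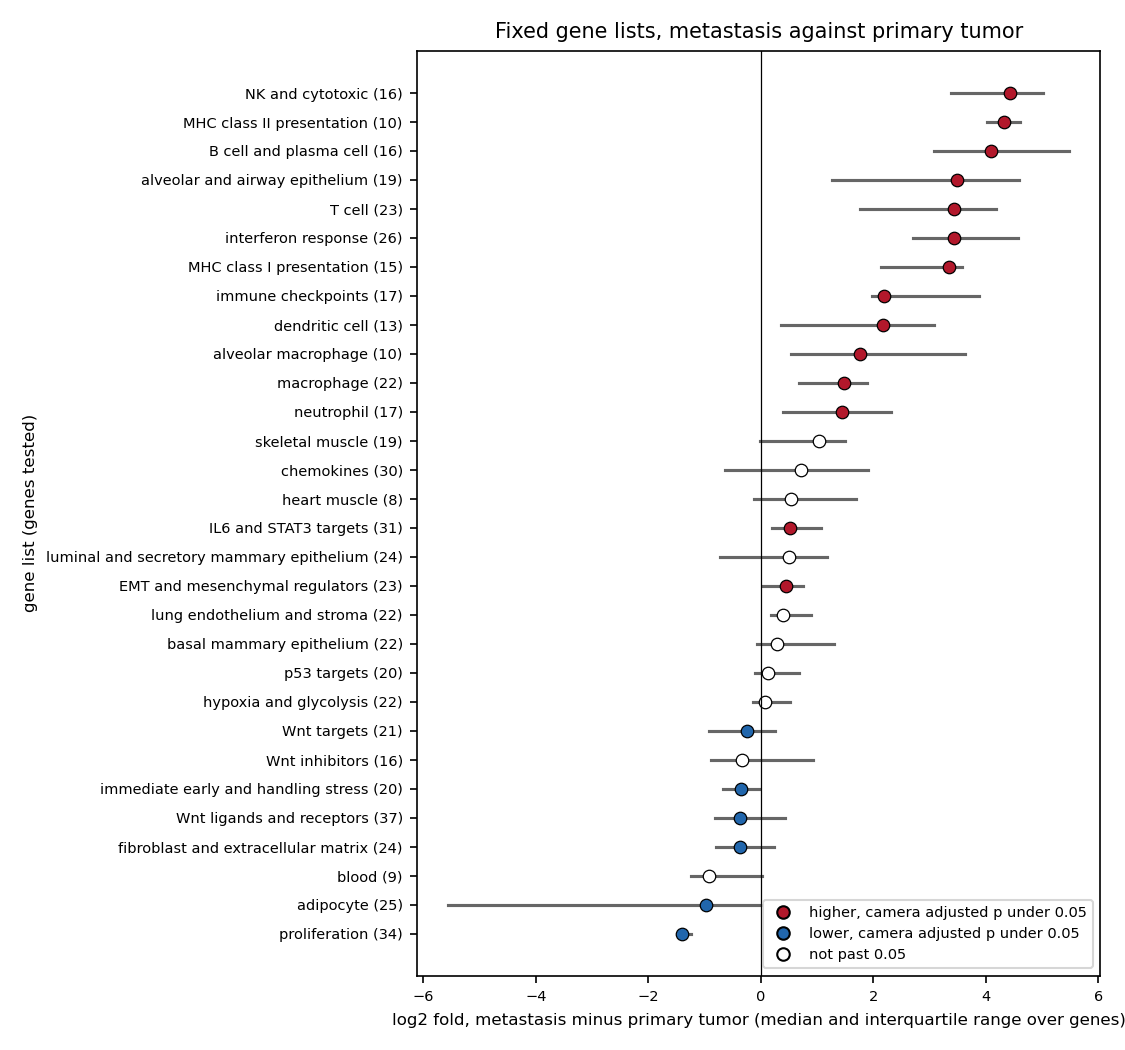
Median log2 fold (points) and interquartile range (bars) over the tested genes of each of the 30 lists (y axis, with the number of genes tested) for metastasis against primary tumor (x axis, log2 fold). NK and cytotoxic genes have a median of 4.42 and proliferation genes one of -1.40, and filled points passed camera with the preset correlation; none passed with an estimated correlation.

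The second comparison set primary tumors against normal mammary gland, the tissue of the primary site. Wnt target genes were higher in the tumors, while Wnt ligands and receptors (11 higher and 15 lower of 37, camera adjusted p = 0.781) and Wnt inhibitors (6 and 7 of 16, or 6 and 8 adjusted over the list alone; camera adjusted p = 0.873) did not pass. Wnt1, on chromosome 15 from 98789857 to 98793837, was at 2.36 ± 1.75 (SD, n = 4) in glands and higher by 9.96 ± 0.89 in tumors (SE; limma adjusted p = 0.000115). Notum rose by 9.86 ± 0.51 and Tnfrsf19 by 6.96 ± 0.49 (SE; limma adjusted p = 1.64e-05 and 4.65e-05), and 14 of 21 Wnt targets rose while 2 fell (15 and 2 adjusted over the list alone; median 2.46; camera adjusted p = 0.000743, and adjusted p = 0.725 with an estimated correlation). Proliferation genes had 28 of 34 members higher (31 adjusted over the list alone; median 3.16; camera adjusted p = 3.32e-05, and adjusted p = 0.725 with an estimated correlation). Their median was 1.60 against glands 1 and 2 alone and 4.57 against glands 3 and 4 alone. Hypoxia and glycolysis genes rose in 14 and fell in 3 of 22 cases (median 1.14), with Car9, which encodes carbonic anhydrase 9, higher by 3.98 ± 0.66 (SE), and 10 of 20 immediate early and handling stress genes rose while 2 fell. These lists had camera adjusted p = 0.0142 and 0.0331, and adjusted p = 0.725 with an estimated correlation for both. Basal epithelial genes went both ways (11 higher and 7 lower of 22, camera adjusted p = 0.36). The basal keratin Krt5 rose by 4.50 ± 0.64 (SE), and the contractile gene Cnn1 fell by 4.25.

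Interferon and MHC class I genes were lower in primary tumors than in mammary gland. Of 26 interferon genes 22 fell and none rose (25 lower adjusted over the list alone; median -2.08; camera adjusted p = 6.06e-08, and adjusted p = 0.725 with an estimated correlation). Iigp1, an interferon-induced GTPase, fell by 3.76 ± 0.34 (SE; limma adjusted p = 0.00012). Of 15 MHC class I genes 13 fell and 1, H2-T23, rose (median -2.46), and H2-D1 fell by 4.35 ± 0.21 (SE). Of 10 MHC class II genes 6 fell (9 adjusted over the list alone), and of 13 dendritic cell genes 11 fell and 1 rose. Camera gave adjusted p = 3.91e-05, 0.0331 and 0.00103 for these 3 lists, and adjusted p = 0.725 with an estimated correlation for each. Interferon genes were lower against either pair of glands, in 22 of 26 cases against glands 1 and 2 and in 26 of 26 against glands 3 and 4. T cell genes depended on the glands: 23 of 23 were lower against glands 1 and 2 (median -6.22), while 11 were higher and 1 lower of 18 tested against glands 3 and 4 (median 1.97). In camera these had adjusted p = 2.87e-10 and 0.0364, and adjusted p = 0.545 and 0.811 with an estimated correlation. Against all 4 glands 3 of 23 T cell genes fell (2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.419).

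All 25 adipocyte genes fell in the tumors (median -7.88; camera adjusted p = 4.39e-12, and adjusted p = 0.725 with an estimated correlation). Thrsp fell by 9.78 and Pck1 fell by 9.17. Of 22 endothelial and stromal genes 15 fell and 3 rose (median -2.83), of 9 blood genes 8 fell (9 adjusted over the list alone), and of 23 EMT genes 12 fell and 2 rose. These lists had camera adjusted p = 0.000743, 0.00931 and 0.0331, and adjusted p = 0.725 with an estimated correlation for each. Of 24 fibroblast genes 11 fell and 2 rose, and of 24 luminal and secretory genes 12 fell. Their camera adjusted p was 0.0142 and 0.048, and adjusted p = 0.798 with an estimated correlation for both. Of 22 macrophage genes 10 fell (camera adjusted p = 0.048, and adjusted p = 0.725 with an estimated correlation). Among IL6 and STAT3 genes 12 rose and 10 fell of 31 and the list did not pass (camera adjusted p = 0.962). Il6 rose by 3.40 ± 0.52 (SE), and its receptor gene Il6ra fell by 3.96 (limma adjusted p = 0.00133 and 2.45e-05). Outside the lists, the transcription factor gene Gata4 was higher by 8.43 ± 0.94 and Jakmip2 by 7.83 ± 0.43, and Tmem45b, with values in 2 primary tumors, fell by 10.93 (limma adjusted p = 0.000305, 1.95e-05 and 1.4e-05).

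In this comparison 5901 genes were higher and 6153 lower of 20866 tested (limma, Benjamini-Hochberg 0.05). Primary tumors and glands shared no sequencing run, so run and tissue cannot be told apart. Setting every library to a common median moved the median fold by 0.41 and gave 8328 higher and 4686 lower. The macrophage call was lost without primary tumor 3817, primary tumor 3819, gland 3 or gland 4 (camera adjusted p = 0.0871, 0.0736, 0.0528 and 0.0603). The luminal call was lost without primary tumor 3817, primary tumor 3820, gland 1 or gland 2 (camera adjusted p = 0.051, 0.0511, 0.0978 and 0.0971), and the EMT and immediate early calls without gland 3 (0.0516 each). Against glands 1 and 2 alone the fibroblast call ended (camera adjusted p = 0.0657, median -0.61), while against glands 3 and 4 alone it had 5.96e-05 (median -3.17), and adjusted p = 0.811 with an estimated correlation. The macrophage, EMT and immediate early calls ended against glands 1 and 2 alone too (camera adjusted p = 0.118, 0.0532 and 0.0705), and the luminal, hypoxia and immediate early calls against glands 3 and 4 alone (0.341, 0.0728 and 0.0703). The NK and cytotoxic, B and plasma cell, checkpoint and skeletal muscle lists passed as lower against glands 1 and 2 alone (camera adjusted p = 5.31e-05, 2.99e-07, 0.00243 and 0.0142, and adjusted p = 0.448, 0.545, 0.545 and 0.545 with an estimated correlation).

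The third comparison set metastases against normal lung. Genes of alveoli, vessels and blood lay far below lung, and basal mammary epithelium genes, 15 higher and 6 lower of 22, did not pass (camera adjusted p = 0.249). Wfdc18, a whey acidic protein family gene, was 17.35 ± 0.30 in metastases and 1.01 ± 0.64 in the 7 lungs with a value (SD), a log2 fold of 16.34 ± 0.40 (SE; limma adjusted p = 1.25e-10). The basal keratin Krt17 was higher by 13.64 ± 0.84, Wnt1 by 11.79 ± 0.57 and the transcription factor gene Tfap2c by 11.39 ± 0.67 (SE; limma adjusted p = 1.54e-07, 2.71e-08 and 1.1e-07). Proliferation genes were higher in 34 of 34 cases (median 3.58) and hypoxia and glycolysis genes higher in 18 and lower in 2 of 22 (median 2.14), with Egln3 and Car9 higher by 4.82 ± 0.55 and 4.78 ± 0.39 (SE). Proliferation had camera adjusted p = 2.24e-13 and hypoxia 1.3e-05, with adjusted p = 0.289 and 0.221 with an estimated correlation.

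Interferon and MHC genes lay above lung as well. Of 26 interferon genes 21 rose and 1 fell (median 2.08; camera adjusted p = 0.000268, and adjusted p = 0.553 with an estimated correlation). Cxcl9 was higher by 9.45 ± 0.36 and Cxcl10 by 5.23 ± 0.43 (SE; limma adjusted p = 6.67e-10 and 3.83e-07), and Ifit3 fell by 1.27, a call lost without metastasis 3820 (limma adjusted p = 0.135). Of 15 MHC class I genes 11 rose and 1 fell (camera adjusted p = 0.00723, and adjusted p = 0.487 with an estimated correlation). Of 17 checkpoint genes 12 rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.0187, and adjusted p = 0.451 with an estimated correlation). Of 10 MHC class II genes 8 rose (camera adjusted p = 0.041, and adjusted p = 0.518 with an estimated correlation). That call ended with common medians (camera adjusted p = 0.0592), without metastasis 3817, metastasis 3819, lung 7 or lung 8 (0.0554, 0.0619, 0.0607 and 0.0614), and without both lungs 7 and 8 (0.105). T, NK and B cell genes of lungs 7 and 8 lay at a median of -3.21 against lungs 1 to 6. The lists of T cell (5 higher and 3 lower of 23, or 2 and 3 adjusted over the list alone), NK and cytotoxic (3 of 16 higher, or 2) and B and plasma cell genes (3 and 3 of 17, or 2 and 3) did not pass, with camera adjusted p of 0.597, 0.712 and 0.657. Without lungs 7 and 8, 11 B and plasma cell genes were lower and 3 higher of 17 (camera adjusted p = 0.0218, and adjusted p = 0.626 with an estimated correlation), and macrophage genes, 14 higher and 4 lower of 22 with camera adjusted p = 0.0756, passed with adjusted p = 0.0173, and adjusted p = 0.448 with an estimated correlation. EMT genes, 7 higher and 12 lower of 23, passed there as well (camera adjusted p = 0.049, and adjusted p = 0.448 with an estimated correlation).

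All 25 endothelial and stromal genes were lower than in lung (median -5.35), as were 24 of 26 alveolar and airway genes (26 adjusted over the list alone; median -4.81), 9 of 9 blood genes (median -7.60), 8 of 10 heart muscle genes and 9 of 19 skeletal muscle genes with 1 higher. The club cell gene Scgb1a1 fell by 8.56 and the endothelial gene Tmem100 fell by 9.30 (limma adjusted p = 4.22e-07 and 1.54e-08). Camera gave adjusted p = 2.1e-14 for endothelial and stromal genes, 1.39e-11 for alveolar and airway genes and 2.07e-06 for blood, and adjusted p = 0.221 with an estimated correlation for each. For heart and skeletal muscle it gave adjusted p = 0.000139 and 0.0187, and adjusted p = 0.289 and 0.66 with an estimated correlation. Adipocyte genes fell in 21 and rose in 1 of 25 cases, fibroblast genes fell in 15 and rose in 2 of 24, alveolar macrophage genes fell in 10 and rose in 2 of 12, and p53 targets fell in 10 and rose in 3 of 20 (11 and 3 adjusted over the list alone). Camera gave adjusted p = 3.48e-05, 0.00175, 0.00318 and 0.03 for these 4 lists, and adjusted p of 0.221, 0.487, 0.487 and 0.451 with an estimated correlation. Wnt targets went both ways, with 11 higher and 6 lower of 21 (camera adjusted p = 0.154), and Sox9 was higher by 6.28 ± 0.21 and Lgr5 by 5.42 ± 0.79 (SE). In total 7844 genes were higher and 5916 lower of 21295 tested (limma, Benjamini-Hochberg 0.05). The metastases and the lungs shared no sequencing run. The pseudogene Rpl7a-ps11 had a fold of 19.64 ± 3.61 (SE), which rests on fractions of a fragment in lung and on fragments shared with its parent gene, so it is uncertain.

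Normal lung was compared with normal mammary gland as a reference for what the host tissues bring. All 25 alveolar and airway genes were higher in lung (median 6.73), all 25 endothelial and stromal genes were higher (median 3.14) and all 25 adipocyte genes lower (median -6.58). These 3 lists passed camera with an estimated correlation too, with adjusted p = 0.00692, 0.0326 and 0.0347. Without lungs 7 and 8 and glands 3 and 4 the alveolar and endothelial lists kept that call (0.0115 and 0.0215) and the adipocyte list lost it (0.186). Another 10 lists passed with the preset correlation but not with an estimated one, where their adjusted p was at most 0.669. The surfactant gene Sftpc was higher by 18.20 ± 0.32 and the leptin gene Lep fell by 10.70 (limma adjusted p = 3.85e-13 and 5.74e-06). Interferon genes were higher in 2 and lower in 8 of 26 cases (9 lower adjusted over the list alone; median -0.45), and the list did not pass (camera adjusted p = 0.156). In total 3901 genes were higher in lung and 4667 lower of 21647 tested (limma, Benjamini-Hochberg 0.05). Lungs and glands shared no sequencing run either. Without lungs 7 and 8 and glands 3 and 4, T cell, B and plasma cell, checkpoint and MHC class I genes passed as lower in lung (camera adjusted p = 1.12e-12, 6.89e-05, 0.00152 and 0.0349) and Wnt ligands and receptors as higher (0.0224), with adjusted p = 0.186, 0.4933, 0.186, 0.497 and 0.249 with an estimated correlation, and the Wnt target call ended (0.0983).

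The difference between the tumor-against-host contrasts at the 2 sites was tested in a fit of all 18 libraries, with positive values where metastasis minus lung exceeded primary tumor minus mammary gland. All 26 interferon genes were positive (median 4.01), as were 14 of 15 MHC class I genes (median 3.80) and 8 of 10 MHC class II genes (9 adjusted over the list alone; median 3.94). Camera gave adjusted p = 4.82e-16, 4.78e-13 and 7.37e-05 for these lists, and adjusted p = 0.167, 0.0616 and 0.267 with an estimated correlation. Cxcl9 differed by 12.41 ± 0.50, Zbp1 by 6.90 ± 0.51 and Nlrc5 by 6.85 ± 0.48 (SE; limma adjusted p = 8.39e-11, 3.19e-08 and 1.88e-08). Wnt targets were negative in 9 and positive in 2 of 21 cases (median -1.15; camera adjusted p = 0.000614, and adjusted p = 0.238 with an estimated correlation), with Notum at -8.41 ± 0.51 and Tnfrsf19 at -6.70 ± 0.48 (SE). Without lungs 7 and 8 and glands 3 and 4 the Wnt target median was -0.66, with 10 negative and 5 positive. Both genes were also higher in normal lung than in gland, Notum by 6.67 ± 0.36 (SE). Proliferation genes had a positive median (0.42) and camera pointed down, without passing (adjusted p = 0.922), and IL6 and STAT3 genes were positive in 6 and negative in 1 of 31 cases (camera adjusted p = 0.922). T cell genes were positive in 4 of 23 cases (3 adjusted over the list alone; camera adjusted p = 0.279) with all libraries, and in 23 of 23 (median 6.42; camera adjusted p = 2.66e-15, and adjusted p = 0.128 with an estimated correlation) without lungs 7 and 8 and glands 3 and 4. Without those 4 libraries 31 of 34 proliferation genes were positive (median 1.63; camera adjusted p = 1.99e-07, and adjusted p = 0.315 with an estimated correlation). NK and cytotoxic genes (13 of 16 positive), B and plasma cell genes (16 of 16) and luminal genes (15 positive and 1 negative of 22) also passed without them, with camera adjusted p = 5.74e-06, 1.99e-07 and 0.00738, and adjusted p = 0.192 with an estimated correlation for each. Without lungs 7 and 8, T cell, NK and B cell genes of metastases lay at medians of -0.13, -0.43 and -1.39 against lung. Those of primary tumors lay at -6.22, -5.37 and -7.50 against glands 1 and 2. The positive differences of these lymphocyte lists therefore came mainly from the gland contrast and show no gain over lung on balance. In total 4052 genes were positive and 2233 negative of 20634 tested (limma, Benjamini-Hochberg 0.05), and with a common median per library 2819 and 3854.

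Genes higher in metastasis than in both primary tumor and lung cannot come from a mixture of those tissues at their measured levels. Of 20634 genes, 385 were higher than both and 150 lower than both (limma, the larger p of the pair of contrasts, Benjamini-Hochberg 0.05). Interferon genes made up 19 of the 385, of 26 tested (21 adjusted over the list alone). Cxcl9, Zbp1 and Cxcl10 were 6.27, 4.80 and 4.43 above the nearer of the other groups on the log2 scale. MHC class I presentation had 8 of 15 genes higher than both (11 adjusted over the list alone), with Nlrc5 above by 4.15, and macrophages 6 of 22 (9), with Aif1 above by 2.05. The checkpoint list had 4 of 17 (8 adjusted over the list alone), among them Cd274, which encodes PD-L1, above by 2.36 with limma adjusted p = 7.38e-06. No gene of the T cell, NK and cytotoxic, or B and plasma cell lists was higher than both, although 2 NK and cytotoxic genes were adjusted over the list alone. All groups share one spread in that fit, and the mean level of the T cell list had an SD of 4.29 in glands and 1.63 in lungs. With that spread Cd8a and Prf1 did not pass even against primary tumor alone. The absence of calls therefore cannot show that no lymphocyte gene lay above both tissues. The largest excess outside the lists was in Sectm1b (6.93), the ubiquitin-like gene Ubd (6.58) and Apol9b (5.95), with limma adjusted p = 0.000692, 0.00142 and 5.11e-05. Of 25 adipocyte genes 9 were lower than both (10 adjusted over the list alone), and Cyp2e1 fell by 5.60 against the nearer group. This count was the least stable: it was 326 without primary tumor 3817, 249 without metastasis 3817, 269 without metastasis 3819 and 1442 without lungs 7 and 8 and glands 3 and 4. With a common median per library 264 genes were higher and 295 lower.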

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

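The tests of lung RNA, of sequencing run, of lymph node tissue and of animals without lymphocytes were chosen after the results were seen. The tests of dilution, of depth and of other splits were chosen before their own outcomes were seen. Dilution and depth nevertheless concern patterns found in these data.

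Interferon, MHC, T cell, NK and B cell genes were higher in metastases than in primary tumors. A mixture of primary tumor with lung at each metastasis's own lung share left a median excess of 3.73, 3.82 and 2.52 on the log2 scale for interferon and MHC genes, which argues against lung RNA as the whole source. For T, NK and B cell genes the excess was 3.63, 3.09 and 2.09, and it was 3.55, 3.04 and 1.85 with lungs 1 to 6 alone. The number of runs that hold both groups was 0, so sequencing run and site cannot be told apart. A difference in immune cells or interferon between the sites is a biological explanation that stays open and may be studied in libraries of both sites from a shared run.

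Proliferation genes were lower in metastases, with a median log2 fold of -1.40. If other cells diluted the tumor cells, genes restricted to the tumor would fall by about as much. The 74 genes at least 16 times higher in primary tumor than in both host tissues had a median of -0.34 (interquartile range -1.17 to 0.12; 14 higher and 33 lower), which argues against dilution as the whole cause. Sequencing run stays open, since 0 runs held both groups. Slower division of the tumor cells at the lung site may also contribute and was not tested.

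Mammary glands 3 and 4 and lungs 7 and 8, from older runs than the other normal libraries, held few transcripts of T, NK and B cells. All 56 genes of the 3 lists were lower in these glands than in glands 1 and 2 (median -6.10), and all 56 in these lungs than in lungs 1 to 6 (median -3.21). The macrophage list was higher in these lungs by a median of 1.18, which argues against low depth, and the difference in the lungs argues against lymph node tissue in glands 1 and 2 as the whole cause. Animals without lymphocytes may explain the pattern, but macrophage genes in the lungs differed by more than the bound of 1 set for that explanation (1.18, against 0.96 in the glands), so it stays open. The labels give no strain for these libraries but end the numbers of these glands and lungs alike, so they may be from the same 2 animals, and run and animals cannot be told apart.

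Of 70 groups of libraries examined for a library far from the rest, 5 had one, and chance gives about 1 in 20. The luminal and secretory list averaged 9.36 in mammary gland 4 and 11.60 to 12.02 in the other glands. The basal epithelium list averaged 12.75 in mammary gland 3 and 11.40 to 11.59 in the others. The Wnt ligand and receptor list averaged 9.96 in lung 7 and 9.66 to 9.77 in the other lungs. The chemokine list averaged 8.64 in lung 8 and 7.87 to 8.12 in the others, and the p53 target list 10.84 in lung 1 and 11.06 to 11.27 in the others.

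The tumor-against-host difference itself differed between the sites for 6285 genes (limma, Benjamini-Hochberg 0.05) and for 17 lists in camera, of which heart muscle also passed with an estimated correlation (camera adjusted p = 0.048). That call ended without lungs 7 and 8 and glands 3 and 4 (0.128). Heart muscle genes averaged 12.13 in lung, and 6.23, 5.87 and 5.85 in metastasis, primary tumor and gland. The heart muscle difference thus follows the level in normal lung. Lists whose tumor-minus-host difference was more positive at the lung site were adipocyte (4.39, where tumors lay below both hosts and the gland level was the highest), interferon response (4.01), MHC class II (3.94), MHC class I (3.80), checkpoints (3.40), macrophage (2.16), dendritic cell (1.97) and hypoxia and glycolysis (1.27). Tumors lay below both hosts for dendritic cell genes too. These averaged 8.15 in metastases and 9.25 in lung, and 6.31 in primary tumors and 9.25 in glands. MHC class II genes averaged 12.48 in metastases and 11.21 in lung, and 8.22 in primary tumors and 10.76 in glands. Their difference thus holds both a rise over lung and a fall below gland. Lists with a negative median were heart muscle (-5.05), blood (-4.59), alveolar and airway epithelium (-3.07), lung endothelium and stroma (-2.96), immediate early genes (-1.30), Wnt targets (-1.15), skeletal muscle (-0.97), neutrophil (-0.79) and Wnt ligands and receptors (-0.32). Normal lung had the highest level of all groups in the heart muscle, blood, alveolar, endothelial, skeletal muscle and neutrophil lists. The same held for Wnt ligands and receptors by a small margin (9.76 in lung and 9.63 in gland). For Wnt targets and immediate early genes primary tumors were highest, but lung lay above gland there too. A lung level above gland makes the difference more negative at the lung site. In Wnt targets metastases also lay below primary tumors (10.88 and 11.27). The neutrophil call was lost without lungs 7 and 8 and glands 3 and 4 (camera adjusted p = 0.0857, median -0.44) and with common medians (0.12), and the skeletal muscle call with common medians (0.129) and without lung 3 (0.0581).

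For metastasis against primary tumor, 1 of 10 splits of the 6 libraries, the real one, called as many genes (9835, with 0 the highest of the others), and 10 splits are too few for a share under 0.05. For the other counts only the real assignment of libraries reached the number of genes called. For primary tumor against mammary gland 1 of 35 splits reached 12054 genes, and the highest other called 10. Of 100 splits drawn, 1 reached the real count for metastasis against lung (13760, highest other 1834, the split that sets lungs 1 to 3, the BALB/c lungs, against the rest). The same held for lung against mammary gland (8568, highest other 827). For the difference between sites (6285) and genes beyond both primary tumor and lung (535), the labels of all 4 groups were shuffled over the 18 libraries. The highest other counts were 2984, where lungs 2 to 4 drew the metastasis label, and 1. Such shuffles mix tissues that differ in any case, so they cannot test either count.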

How the results depend on the processing

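Fits without lungs 7 and 8 or glands 3 and 4, or with their number endings as a block, were added after seeing the data. Total counts of genes and lists stayed within 1.5 times of those reported under the scalings, the filter, the added constant and the fit without trend, but a common median turned the balance of directions for metastasis against primary tumor (3766 higher and 7686 lower), the difference between sites (2819 and 3854), genes beyond both primary tumor and lung (264 and 295) and primary tumor against mammary gland (8328 and 4686). Exceptions follow, and the cause was not tested unless the setting itself removes genes or libraries. For metastasis against primary tumor, 4168 genes passed with at least a 2-fold change and 4128 with all 4 groups in one fit. Library weights gave 13442 genes for lung against mammary gland, 12190 for the difference between sites and 3479 for genes beyond both primary tumor and lung. The last count was 1442 without lungs 7 and 8 and glands 3 and 4. With an estimated correlation 0 lists passed for metastasis against primary tumor, 0 for primary tumor against mammary gland, 0 for metastasis against lung, 3 for lung against mammary gland and 1 for the difference between sites, where the preset gave 20, 15, 15, 13 and 17 and fry 22, 20, 23, 20 and 20. Leaving out 1 library at a time gave 7625 to 9949 genes for metastasis against primary tumor, 9385 to 12116 for primary tumor against mammary gland, 11827 to 13999 for metastasis against lung, 7449 to 8659 for lung against mammary gland, 5154 to 6527 for the difference between sites and 249 to 698 for genes beyond both (326 without primary tumor 3817, 249 without metastasis 3817 and 269 without metastasis 3819). The lists past the threshold ranged from 17 to 21, 14 to 15, 14 to 15, 13 to 14 and 16 to 19, and the Trp53 difference from 1.04 to 1.10. Directions turned for T cell genes against glands 3 and 4 only (camera adjusted p = 0.0364, 0.811 with an estimated correlation), and, without lungs 7 and 8 and glands 3 and 4, for B cell genes between lung and gland (6.892e-05, 0.4933 estimated) and for fibroblast (0.0166, 0.599 estimated) and proliferation genes (1.99e-07, 0.315 estimated) in the difference between sites. Proliferation genes turned there without mammary gland 4 too (0.0237), and the adjusted p reached 0.967 without lung 6. The lung share averaged 3.09%, 2.75% with BALB/c lungs only and 0.584% from lung endothelium and stroma genes. Deviations of same-numbered primary tumors and metastases correlated at -0.098, -0.018 and -0.064 across 14124 genes. With 3 libraries per site centred on their mean, these correlations cannot settle whether the tumor numbers mark animals. With the number as a block 8915 genes passed, 8693 of them also without it, 20 lists passed, and 509 genes lay beyond both groups. With the number endings of glands 3 and 4 and lungs 7 and 8 as a block, 9160 genes passed for lung against mammary gland, 6385 for the difference between sites and 537 beyond both; the gland difference and the lung difference correlated at 0.042 across 14822 genes. The consensus correlations of this block were 0.383 and 0.352, which any shared deviation of the 4 libraries from their groups also raises, so whether the endings mark animals stays open. Single named genes gave 169 results with 3662 alternatives, of which 3574 kept side and direction, 81 were lost, 7 gained and 0 turned; 150 lists gave 2250, with 2054, 122, 69 and 5. Depth limits genes near 1 fragment, whose folds rest on a few fragments.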

Other observations

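Levels of single genes differed between tumor and host pieces. Aire, a transcription factor gene known from thymic epithelium, was 9.74 ± 0.59 in primary tumors and 12.61 ± 0.29 in metastases (SD, n = 3 each), against 1.04 ± 1.15 in the 7 lungs with a value (limma adjusted p = 2.76e-08 for metastasis against lung). Wnt10a was 10.85 ± 0.02 in primary tumors, 11.08 ± 0.57 in metastases and 6.46 ± 1.53 in mammary glands (SD). Wnt2, a ligand gene of lung mesenchyme, was 11.04 ± 0.56 in lungs, 8.85 ± 1.44 in glands, 5.66 ± 1.03 in primary tumors and 3.84 ± 0.84 in metastases (SD). Lif, which encodes a cytokine of the IL6 family, was higher in metastases than in lungs by 3.60 ± 0.32 (SE; limma adjusted p = 6.95e-07).

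Checkpoint genes differed in where they were high. Vtcn1 was 10.37 ± 0.08 in primary tumors, 12.34 ± 0.38 in metastases, 9.55 ± 1.57 in mammary glands and 8.12 ± 0.46 in lungs (SD). Ido1, an enzyme of tryptophan breakdown induced by interferon, was 9.04 ± 1.68 in glands, 5.46 ± 0.42 in lungs and 5.36 ± 1.08 in metastases, and about 1 fragment in the 2 primary tumors with a value. Among complement genes of macrophages, C1qc was higher in metastases than in lungs by 4.12 ± 0.32 (SE; limma adjusted p = 1.92e-07), while the neutrophil gene Retnlg fell by 7.06.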
